A study of Homo sapiens with 5 samples.

How the data were processed

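The series maps RNA bound by SRSF9, a serine/arginine-rich splicing factor, in HEK 293T cells, a human embryonic kidney cell line. Binding was mapped by eCLIP, in which protein-bound RNA is fragmented, immunoprecipitated with its protein, recovered from a membrane and sequenced. Per the labels, 2 libraries came from cells overexpressing SRSF9 alone and 2 from cells overexpressing SRSF9 together with ADAR2, an adenosine deaminase that converts adenosine to inosine in double-stranded RNA. A further library was input RNA from cells overexpressing both proteins. No input library from cells with SRSF9 alone was used here. The sample labels name an antibody against SRSF9, while the labels' extraction protocol names beads coupled for MYC. Nothing in the labels says whether the 2 libraries of a condition came from separate cultures, so every test over libraries measures only the spread between these libraries, which may be technical.

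The deposited data used here are 1 table of 80514 peaks for the whole series. It has no header, no strand, no gene name and no read count. Each row gives a position, 4 log2 values and a class of the peak as present with ADAR2, without ADAR2 or in both conditions. The submitters' processing notes name the hg19 build. The aligner, peak caller, annotation, thresholds and treatment of replicates are not given in the sources used here. The deposited values are log2 ratios made by the authors, and the table does not name their denominator. They were read as log2 because in 3 of the 4 columns 47.8% to 52.9% of the values with at most 3 decimals fell on log2 of ratios of small whole numbers plus 1 constant. The second SRSF9-only column showed no such clear constant and was read on the same scale as the others. The series holds 1 input library, which may be the denominator, but no source states this. A value of 0 stands as a placeholder in the columns of the condition in which a peak is absent. In all 71949 rows classed as with ADAR2 the first pair of columns held this placeholder, and in all 4763 rows classed as without ADAR2 the second pair held it. The pairs were assigned to the conditions on that basis. Within a pair the columns carry no replicate name, and they are called the first and second library of a condition in file order.

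In all 8565 peaks present without ADAR2 and in all 75751 peaks present with ADAR2, the 2 libraries of the condition had values of the same sign. No row of one class shared a nucleotide with a row of another class. Some values have more than 3 decimals, as a mean over several peaks would. These made up 28.4% of the shared rows in the second SRSF9-only library and 0% in the first. Of the shared rows, 157 repeated the coordinates of an earlier row, and rows with identical coordinates were averaged to 3645 shared regions before values were compared. The depth of the libraries is not in the table, so no interval on a single log2 value was computed.

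The annotation at hand, GENCODE release 29, is on GRCh38. At their deposited coordinates 8.38% of the peaks outside the mitochondrial chromosome touched a GRCh38 exon, against 5.98% and 6.25% after moving them by 1 Mb in either direction, so its exons were not used. Genes were therefore not named, and peaks are given by hg19 position, counted from 1. The gene lists, single genes, transcript regions and sequence motifs planned before the data were examined were not analysed here for the same reason. The plan provided for naming peaks by position in that case. The use of chromosomes in place of transcript regions, and of fixed windows of 100 kb in place of genes, was chosen after the data were examined.

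Shares carry 95% Wilson intervals, which cover counting error over peaks only. Chromosomes and windows with at least 5 exclusive peaks were tested with Fisher's exact test, two-sided, on peaks found only without ADAR2 against peaks found only with ADAR2, with Benjamini-Hochberg adjustment and a threshold of 0.05. Those tests run across peaks, which are not biological replicates and of which neighbours are not independent. Peak widths were compared by a two-sided permutation test of the difference in medians with 100000 resamples. The 3645 shared regions were compared between conditions with limma on the deposited log2 values, with 2 libraries per condition and Benjamini-Hochberg adjustment. The plan had foreseen unlogged values and a pseudocount of 1, and none was added because the values were already on a log2 scale. limma's estimate gave the same standard error of 0.591 to every region, since its prior degrees of freedom were infinite.

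Proximity was the share of peaks with a peak of the other condition within 100 nt, 1 kb or 10 kb, compared with the same peaks moved by 100 kb. It, the counts above thresholds and the comparison of peaks below 0 were added after the data were examined. The rule for naming was set for genes before the data were examined and was applied to positions. It took the 10 windows with most peaks in each class, the 10 windows past the threshold with the largest odds ratio, the 5 with the smallest p in a direction where none passed, and the 5 peaks with the highest mean value in each class. It also took the 10 peaks with the largest change past the threshold in each direction, which the plan had tied to read counts and which was applied here to the log2 values of the shared regions. Peaks with the lowest values were added after their values were seen. Alternatives tried were merging of neighbouring peaks, peaks above the median of the mean log2 value, removal of the mitochondrial chromosome, a width of at least 20 nt, other minimum numbers of peaks, trimming of widths, a filter on mean value, centring of each column on its median, and leaving out each library in turn. Settings that could not be applied to these values are named in the closing section.

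The tests were tested on simulated data. Of 200 windows changed among 5362, 3.5% were recovered at an odds ratio of 5, 38.5% at 10 and 72.5% at 20, with 0 false calls. In 20 shuffles of the class over peaks, at most 0 windows and 1 chromosome passed. Classes were drawn for each peak separately in both, so these numbers do not cover false calls from neighbouring peaks that are not independent. Among 3645 simulated shared regions, drawn with the residual SD of 0.591 that limma used for the real regions, limma recovered 8% of the regions changed by 1 on the log2 scale, 60% of those changed by 2 and 96% of those changed by 3, with 10 false calls. With a lower SD of 0.445, which leaves out the mean difference between libraries, it recovered 10%, 86% and 100%, with 2 false calls. Neither simulation held a difference common to all regions of a library, so their false calls do not cover that case. Analyses used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.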

Results

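SRSF9-bound RNA was mapped by eCLIP in HEK 293T cells that overexpressed SRSF9 alone or SRSF9 together with ADAR2, with 2 libraries per condition. The study asked where SRSF9 binds with and without ADAR2, in work on how SRSF9 represses editing at ADAR2 targets. The deposited table held 80514 peaks with the authors' log2 ratio in each library of the condition in which a peak was found. Read depths were not in the table and are unknown here. All positions are on hg19.

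Most SRSF9 peaks in the table were classed as present only with ADAR2 co-expressed. The class tells where a peak was called and kept, which is not the same as where SRSF9 bound. Of the peaks classed as with ADAR2 only, 5324 had ratios below 0 in both libraries. Of all peaks, 71949 were classed as with ADAR2 only, which is 89.4% (95% Wilson interval 89.1 to 89.6). A further 4763 peaks, 5.92% (5.75 to 6.08), were found without ADAR2 only, and 3802, 4.72% (4.58 to 4.87), were shared. The condition with ADAR2 thus had 75751 peaks and the condition without had 8565, a ratio of 8.84. The peaks covered 2871666 nt with ADAR2 and 385473 nt without. Shared peaks made up 44.4% (43.3 to 45.4) of the peaks without ADAR2 and 5.02% (4.87 to 5.18) of those with it. The table gives 1 peak set per condition, so these counts have no spread between libraries and were not tested between conditions.

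Peaks found without ADAR2 lay close to peaks found with it, even where they did not overlap. Of the 4763 peaks found only without ADAR2, 23.9% (22.7 to 25.1) had a peak of the other condition within 100 nt and 63.2% (61.8 to 64.6) within 1 kb. Within 10 kb it was 4526 of the 4763. Moved by 100 kb in either direction, 10.1% and 11.6% of them lay within 1 kb of such a peak and 38.0% and 38.7% within 10 kb. Peaks with ADAR2 also lay close to each other. Of those found only with ADAR2, 52.6% had another peak of their own condition within 1 kb and 90.5% within 10 kb. Of the peaks found only with ADAR2, 10.3% (10.1 to 10.5) had a peak without ADAR2 within 1 kb, against 1.42% and 1.40% after moving them. In windows of 100 kb, 2993 of the 3035 windows with a peak without ADAR2, 98.6%, also held a peak with ADAR2. Shared peaks counted for both conditions there. Of all 9782 windows with a peak, 9740 held one with ADAR2, so the 98.6% says nothing further about closeness. Of the 9740 windows with a peak with ADAR2, 30.7% held one without it.

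Shared peaks were the widest. Their median width was 51 nt (quartiles 33 and 75), against 34 nt (20 and 49) for peaks only with ADAR2 and 32 nt (19 and 46) for peaks only without it. The difference of 17 nt between shared peaks and peaks only with ADAR2 had an adjusted p of 2e-05 in the permutation test across peaks, based on the smallest p that the permutations can give. Peaks only without ADAR2 were 2 nt narrower than peaks only with it, with a permutation p of 0.00574. How the interval of a shared peak was set is not given in the sources used here. The permutation test takes no account of it, so the larger width may come from the way shared peaks were defined.

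The second SRSF9-only library had the lowest log2 ratios. The median was 1.07 in the first and 0.24 in the second SRSF9-only library over 8565 peaks, and 1.16 and 1.06 in the libraries with ADAR2 over 75751 peaks. In the 3645 shared regions, the same in every library, the medians were 0.95 and 0.20 without ADAR2 and 1.31 and 1.02 with it. Within a peak the first SRSF9-only library exceeded the second by a median of 0.84 (quartiles 0.38 and 1.32), while the libraries with ADAR2 differed by a median of 0.05 (-0.31 and 0.54). In the second SRSF9-only library 2153 values lay between 0 and 0.25 and 225 between -0.25 and 0. In the first these numbers were 250 and 1012. The number of peaks above a fixed ratio depends on the scale of each library. With a log2 ratio above 1 required in both libraries of a condition, 790 peaks remained without ADAR2 and 32610 with it, a ratio of 41.3. By the first library alone the corresponding numbers were 4646 and 44848, and by the second alone 819 and 40535. Above 2 in both libraries there were 46 and 7279 peaks, and above 3 there were 2 and 550. By the first library alone there were 1768 and 14061 above 2, and 151 and 1884 above 3. By the second alone these were 53 and 12197, and 2 and 1615.

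**Figure D1:**
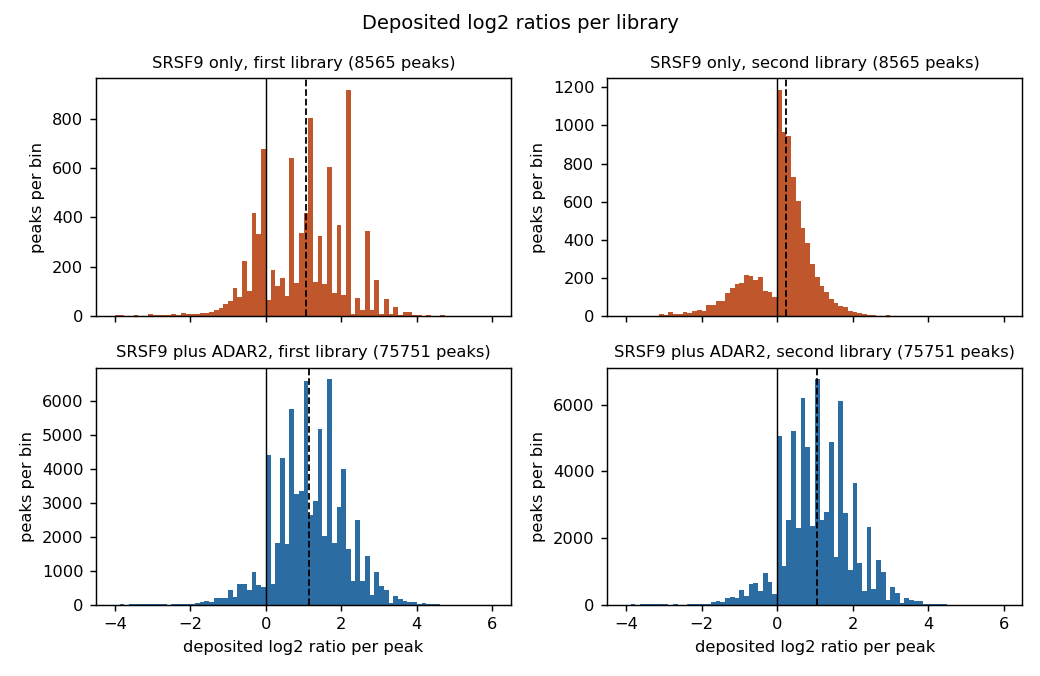
Histograms of the deposited log2 ratio per peak (x axis) in each library, with the number of peaks per bin on the y axis; dashed lines mark the medians and values under -4 are not drawn. The second SRSF9-only library is centred near 0, with a median of 0.24, while the other 3 libraries have medians of 1.06 to 1.16.

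Peaks with the highest mean ratio lay on several chromosomes in each class. Among peaks found only with ADAR2, the highest mean was 4.72, on chromosome 3 from 40498992 to 40499042, with 5.26 and 4.19 in the 2 libraries. It was followed by chromosome 8 from 125486272 to 125486372, with a mean of 4.65, and chromosome 19 from 50189216 to 50189241, with 4.62. The highest peaks found only without ADAR2 were on the mitochondrial chromosome from 10016 to 10053, with 4.66 and 3.01, and on chromosome 1 from 77955315 to 77955338, with 4.36 and 3.16. The highest shared peak lay on chromosome 14 from 21463336 to 21463396, with 1.66 and 2.14 without ADAR2 and 4.04 and 3.72 with it. A second shared peak on chromosome 14, from 45578936 to 45578975, had 1.66 and 1.38 without ADAR2 and 3.88 and 4.23 with it.

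Peaks with a ratio below 0 in both libraries were more common without ADAR2. They made up 23.4% (22.2 to 24.6) of peaks found only without ADAR2 and 7.40% (7.21 to 7.59) of peaks found only with it, an odds ratio of 3.82 (Fisher's exact test across peaks, p = 2.71e-236). Among the 3802 shared peaks, 852 were below 0 without ADAR2 and above 0 with it, and 84 switched the other way. These counts depend on where 0 lies on each library's scale, and a shift of a whole library moves them. Between -0.25 and 0 lay 1012 of the 8565 values in the first SRSF9-only library and 225 in the second. With ADAR2 these were 1096 and 1032 of 75751 values. The peak furthest below 0 was found only with ADAR2, on chromosome 14 from 50053318 to 50053335, with -10.22 and -9.55. A shared peak on chromosome 14, from 50320559 to 50320592, had -5.31 and -3.52 without ADAR2 and -7.35 and -6.69 with it. Of peaks found only without ADAR2, the lowest lay on chromosome 2 from 118847164 to 118847185, with -3.85 and -3.46, and another lay on chromosome 9 from 35657781 to 35657826, with -2.88 and -3.02. These peaks with the lowest values were chosen after their values were seen.

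In the 3645 shared regions, the ratio was more often higher with ADAR2 than lower. The median difference, with minus without, was 0.62 on the log2 scale, and 73.6% of the regions were higher with ADAR2. By limma with Benjamini-Hochberg adjustment, 675 regions rose and 88 fell with ADAR2, at n = 2 libraries per condition. With each library centred on its own median, which moved the median difference to 0.03, 459 regions were higher and 396 lower. Both libraries with ADAR2 exceeded both without in 49.9% of regions and lay below both in 9.22%, where chance gives 16.7% each, and after centring these shares were 33.8% and 30.5%. That chance value takes no account of the table holding only peaks whose libraries of a condition had the same sign, which brings those libraries closer together. Among the 2528 regions above 0 in every library, 82 passed, and among the 1821 above the median mean ratio, 146 passed. Without the first SRSF9-only library, limma called 0 regions (1405 at an unadjusted p under 0.05), and without the second it also called 0 (1051 unadjusted), with a median difference of 0.99 and 0.27. Without the first or the second library with ADAR2 it called 81 and 221 regions.

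The 10 regions that rose most with ADAR2 rose by 3.92 to 4.86 on the log2 scale, and all 10 were below 0 on average without ADAR2 and above 0 with it. On chromosome 20 from 61441051 to 61441110 the ratio was -1.01 ± 1.32 (SD, n = 2) without ADAR2 and 3.84 ± 0.117 (SD, n = 2) with it. That difference of 4.86 ± 0.59 (SE) had a limma adjusted p of 8.08e-13, and of 3.74e-06 after centring. Before centring limma gave the same SE to every region, so the first of these p-values does not use the region's own spread. On chromosome 2 from 86350827 to 86350890 the ratio was -0.55 ± 0.30 and 4.26 ± 0.56, and on chromosome 19 from 47634465 to 47634533 it was -0.09 ± 0.011 and 4.12 ± 0.21 (SD, n = 2 each). The first SRSF9-only value was -0.079 both there and on chromosome 20, which is also that library's first quartile over the shared regions. Many values of that library fell on ratios of small whole numbers. An SD of 0.011 and a value just below 0 therefore do not show close replication or a firm change of sign. Also among the 10 regions that rose most were those on chromosome 1 from 153930915 to 153930992 and on chromosome 6 from 76364963 to 76365000, the former rising by 4.62. Of the 10 regions that fell most with ADAR2, 8 were above 0 without it and below 0 with it, and 2 were below 0 in both conditions. On chromosome 2 from 133012571 to 133012624 the ratio was 2.75 ± 0.13 without ADAR2 and -1.75 ± 0.59 with it (SD, n = 2 each). That difference of -4.50 ± 0.59 (SE) had a limma adjusted p of 1.89e-11, and of 9.33e-07 after centring. Regions of the mitochondrial chromosome from 4433 to 4461 and from 12171 to 12204 had differences of -4.34 and -4.01. The latter ranged from -2.74 to -5.27 when 1 library was left out. On chromosome 12 from 50850476 to 50850518 the mean ratio was -2.51 without ADAR2 and -6.79 with it. The 10 regions that rose also passed by limma after centring, which enlarges the change of those that fell. All 20 kept their direction in every fit without 1 library. Those that changed sign between conditions could not reverse there, because the libraries of a condition always had the same sign. The 20 regions were also picked for large changes in these same libraries, so neither their direction nor their size in those fits is separate support. Without the first or the second SRSF9-only library their median size of change was 4.26 and 4.04, against 4.12 with all libraries. None of the 20 passed in those fits, in which limma's prior degrees of freedom were 3.76, against an infinite number with all libraries. Without the first library with ADAR2 18 passed, and the mitochondrial region from 12171 to 12204 (limma adjusted p = 0.0505) and that on chromosome 10 from 101996939 to 101997021 (limma adjusted p = 0.220) did not.

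**Figure D2:**
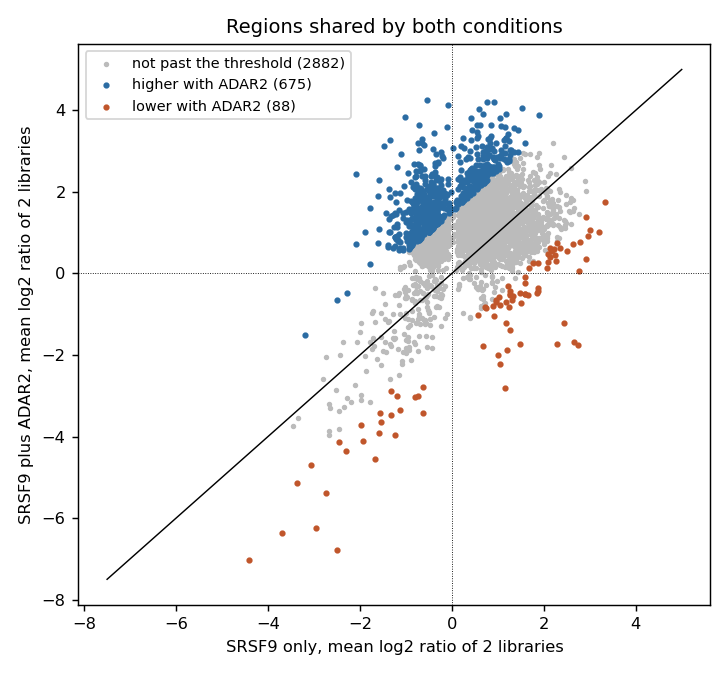
Mean log2 ratio of the 2 SRSF9-only libraries (x axis) against that of the 2 libraries with ADAR2 (y axis) for the 3645 shared regions; the solid line marks equal values. The 675 regions called higher with ADAR2 by limma lie above the line and the 88 called lower lie below it, before centring of the libraries.

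Mitochondrial RNA took a larger share of the peaks without ADAR2. The mitochondrial chromosome held 72 peaks without ADAR2, 0.841% (0.668 to 1.06) of that condition, and 80 with it, 0.106% (0.0849 to 0.131). These numbers were close, and the shares differed mainly through the totals of 8565 and 75751 peaks. Of the mitochondrial peaks, 51 were shared, 21 were found only without ADAR2 and 29 only with it, which is 0.441% and 0.0403% of the exclusive peaks of each condition (Fisher's exact test across peaks, adjusted p = 1.20e-11 over 24 chromosomes). All 80 mitochondrial peaks with ADAR2 were below 0 in both libraries, as were 60 of the 72 without it, 83.3% (73.1 to 90.2).

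The exclusive peaks were also spread unevenly over the nuclear chromosomes. Among chromosomes with an adjusted p under 0.05 (Fisher's exact test across peaks), 8 held a larger share of the peaks found only without ADAR2. These 8 included the mitochondrial chromosome. A further 6 past the threshold held a larger share of those found only with ADAR2. Chromosome 17 held 8.29% of the peaks found only without ADAR2 and 5.89% of those found only with it (adjusted p = 1.06e-09, Fisher's exact test). Chromosomes 5 and 6 held 6.36% and 5.90% of the former and 4.54% and 4.24% of the latter. Chromosome 9 held 2.10% against 3.90% (adjusted p = 1.53e-10), and chromosome 22 held 1.97% against 3.29%. Counting each 100 kb window once per class left 2 of the 13 nuclear chromosomes past the threshold, chromosome 17 (adjusted p = 0.000179) and chromosome 9 (adjusted p = 0.00045). The mitochondrial chromosome, a single window, could not be tested in that way.

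**Figure D3:**
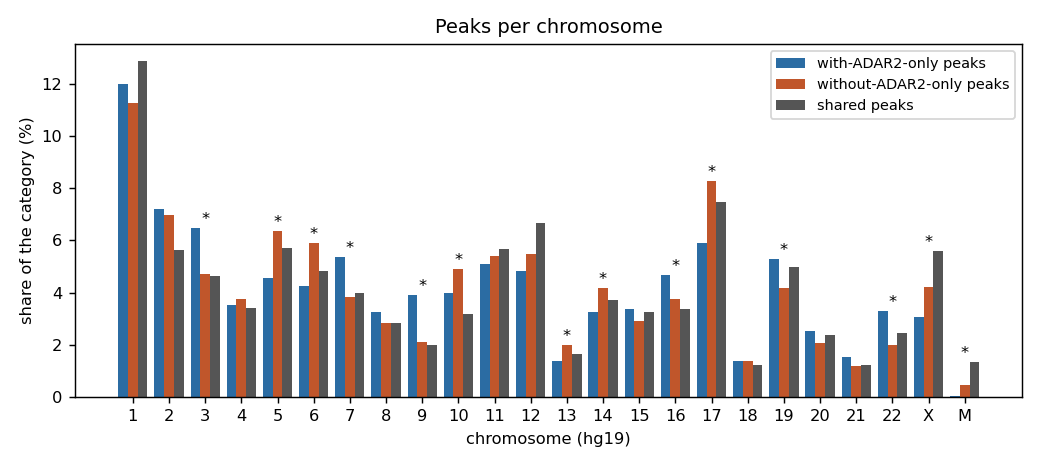
Share of each peak class (y axis, percent of the class) on each hg19 chromosome (x axis), with M the mitochondrial chromosome; asterisks mark an adjusted p under 0.05 in Fisher's exact test across peaks between the 2 exclusive classes. Chromosome 17 holds 8.29% of peaks found only without ADAR2 against 5.89% with it, and chromosome 9 holds 2.10% against 3.90%.

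Some windows held more peaks found only without ADAR2 than their share over all windows. Of 5362 windows of 100 kb tested, 52 held a larger share of them than the 6.21% over all exclusive peaks, and 0 held a smaller share (Fisher's exact test with Benjamini-Hochberg adjustment; at an unadjusted p under 0.05 there were 369 and 0). A smaller share could not be detected at these numbers of peaks. On chromosome 19 from 42900001 to 43000000, with 59 peaks only with ADAR2 and 0 only without, Fisher's exact test gave p = 0.0515 before adjustment. The 52 windows held 9.55% of the peaks found only without ADAR2, which lay in 2343 windows, 7.36% of the shared peaks and 1.08% of the peaks found only with ADAR2. Among peaks above the median of all mean ratios, which kept 36.4% of the peaks found only without ADAR2, 0 windows passed, and among peaks above the median of their own class 7 passed. With peaks of a class within 1 kb merged, 14 windows passed.

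The window with most peaks found only without ADAR2 was on chromosome 11 from 65200001 to 65300000, with 28 such peaks, 32 only with ADAR2 and 23 shared (odds ratio 13.3, Fisher's exact test, adjusted p = 1.16e-14). A window on chromosome 1 from 245000001 to 245100000 had 17 peaks only without ADAR2, 19 only with it and 18 shared (odds ratio 13.6, and 0 among peaks above the median of all mean ratios). On chromosome X from 73000001 to 73100000 there were 15, 37 and 42, and on chromosome 10 from 28800001 to 28900000 there were 16, 45 and 3. All 10 windows with most peaks found only without ADAR2 passed the test, but they were picked by a count that the test uses. With peaks of a class within 1 kb merged, those on chromosome 11 and on chromosome 1 from 245000001 did not pass (odds ratio 5.92 and adjusted p = 0.393 for each, Fisher's exact test). Odds ratios were highest on chromosome X from 102800001 to 102900000, with 5 peaks only without ADAR2 and 1 only with it, and on chromosome 4 from 186300001 to 186400000, with 4 and 1. After merging, both held too few peaks to be tested. On chromosome 6 from 35800001 to 35900000 there were 11 peaks only without ADAR2, 5 only with it and 0 shared (odds ratio 33.3, adjusted p = 2.29e-07, and 19.0 with an adjusted p of 0.00267 after the same merging). On chromosome 14 from 102500001 to 102600000 there were 12 and 8 (odds ratio 22.7, and 7.89 without passing after the same merging), and on chromosome 8 from 134200001 to 134300000 there were 12 and 11.

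None of the 10 windows with most peaks found only with ADAR2, which held 49 to 61 such peaks, passed the test. A larger share with ADAR2 could not be detected at these numbers of peaks, so this does not set the conditions apart. They included chromosome 3 from 184000001 to 184100000, with 61 peaks only with ADAR2, 9 only without and 14 shared, and chromosome 1 from 1200001 to 1300000, with 58, 2 and 2. On chromosome 16 the neighbouring windows from 89400001 to 89600000 held 51 and 56 peaks only with ADAR2. The window on chromosome 5 from 179000001 to 179100000 held 18 shared peaks, 16 only with ADAR2 and 2 only without. The 5 windows with the smallest p in the direction of ADAR2 had 42 to 59 peaks only with ADAR2 and 0 only without.

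**Figure D4:**
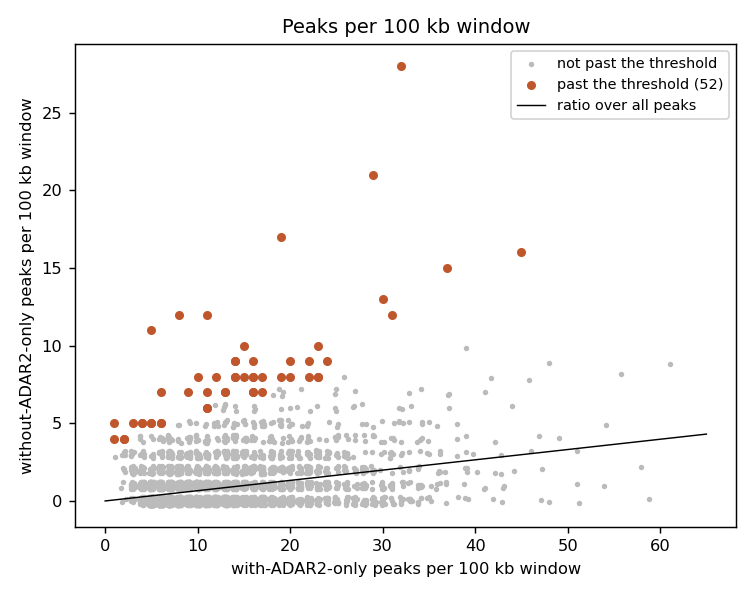
Peaks found only with ADAR2 (x axis) against peaks found only without ADAR2 (y axis) in each 100 kb window with at least 5 peaks; the line is the ratio over all exclusive peaks, and grey points are moved slightly at random so that they do not hide each other. The 52 windows past the threshold all lie above the line, the highest with 28 peaks found only without ADAR2.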

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

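The alternatives with peaks above 0, peaks above the median of their own class, centring, merging within 1 kb, windows or regions without the mitochondrial chromosome, and all those for peaks below 0 were chosen after seeing the data. No paired analysis was possible because the value columns carry no replicate numbers. The share of peaks found only with ADAR2, 89.4%, was 92.1% among peaks above the median mean log2 ratio, 88.9% among peaks of at least 20 nt and 91.4% among peaks above 0 in every library of their condition. The shared part of the peaks without ADAR2, 44.4%, was 49.2% among peaks of at least 20 nt, 41.9% among peaks above 0 and 22.9% among peaks above the median of each condition, where independent medians alone would give 22.2%. Of the peaks above the median without ADAR2, 37.7% were shared, and 52.5% of all shared peaks lay above the median with it. Merging overlaps and removing the mitochondrial chromosome left the shares of 89.4% and 44.4% within their intervals. Of 14 chromosomes, 13 of them nuclear, counting each window once per class left 2, with the mitochondrial chromosome not testable as a single window, and the other alternatives gave 12 to 15. The 52 windows became 0 among peaks above the median of all peaks and 7 among peaks above the median of their class, and 14 with peaks of a class within 1 kb merged, all 3 with fewer peaks tested, and the other alternatives gave 44 to 60. The 763 shared regions past the limma threshold became 146 of the 1821 above the median mean value and 82 of the 2528 above 0 in all 4 columns, a filter that leaves out regions that changed sign. Leaving out 1 library gave 0 to 221, where the lone library is assumed to vary like those of the other condition. The 2 fits with 0 were those without an SRSF9-only library, where limma's prior degrees of freedom fell to 3.76 while its prior SD was 0.39, below the 0.59 with all libraries. Except where stated, the cause was not tested. The width difference stayed at -2 nt, and the odds ratio for peaks below 0 ranged from 3.79 to 3.98. None of the settings for peaks below 0 moved the 0 of a library, so they do not test how far that ratio depends on it. Over the named windows under other settings, 85 comparisons kept the call, 25 lost it and 1 reversed: chromosome 1 from 245000001 to 245100000, whose odds ratio of 13.6 became 0 among peaks above the median of all peaks (adjusted p = 1). In 2 settings the mitochondrial window had 0 peaks only with ADAR2 and so no finite odds ratio. For the named shared regions 84 comparisons kept the call, 42 lost it and 0 reversed. Leaving out a library could not reverse those that changed sign between conditions. Not run were the stricter overlap and the comparison with strand (no strand and no separate intervals in the table), other pseudocounts (values already on a log scale), and the alternatives for read counts, the replicate block, gene lists and sequence. The numbers of reads behind the ratios limit their precision and are unknown here.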

Other observations

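The tests of the number of peaks and of the shared regions were chosen after those results were seen, and the tests of merged windows and of windows with peaks below 0 before their results were seen. Part of the peaks below 0 came together at certain positions. Over both conditions 6851 peaks, 8.51%, had a mean ratio below 0, and 234 windows of 100 kb held at least 5 of them. In 100 shuffles of the sign over peaks of the same class the highest number of such windows was 148 and the median 128. The 234 windows held 1693 of the peaks below 0, 24.7%, and 8.80% of all peaks. They were picked by their number of peaks below 0, so a larger share of these follows from the choice. The shuffles also took peaks as independent, which neighbours are not. The mitochondrial chromosome had 91 of its 101 peaks below 0. On chromosome X from 73000001 to 73100000 it was 42 of 94 peaks, on chromosome 10 from 96300001 to 96400000 it was 21 of 56, and on chromosome 11 from 65200001 to 65300000 it was 20 of 83. The RNAs transcribed there were not identified here.

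The condition without ADAR2 had fewer peaks than the condition with ADAR2, by a ratio of 8.84. One technical explanation is that the 2 SRSF9-only libraries had unequal ratios and only peaks of equal sign were kept. The pile of values just above 0 in the second library would go with this. In the first library more values lay between -0.25 and 0 than between 0 and 0.25, 1012 against 250. Among peaks above 3 in the first library the ratio of with to without was 12.5, and among those above 2.5 it was 7.72. Of such peaks without ADAR2, 4.64% and 9.97% had a second value under 0.25. Whether unequal signs are the whole cause cannot be decided from these values, because peaks dropped by that rule are not seen. The ratios also depend on the scale of each library. A lower depth of the first SRSF9-only library stays open: read as depth over a common denominator, the column constants put the first library with ADAR2 at 1.504 times its depth, but the next best constant of that column, which fits 44.7% of its values against 52.9%, turns this ratio round, and the same reading puts the second SRSF9-only library at 19.2 times the first. ADAR2 itself, the difference that the design names, was not tested apart from the libraries and stays open.

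Shared regions had higher ratios with ADAR2, by a median of 0.62 on the log2 scale (0.6175). Whether this surplus is 1 constant difference per library or a change of most regions cannot be told apart, because centring removes either. After centring, 459 of the 675 regions were still called higher, and 396 regions were called lower. That fit used its own spread, from which centring had removed the difference in median between libraries. Centring also leaves the SDs of the columns unequal, 0.77 in the second SRSF9-only library and 1.08 in the first. These calls therefore cannot decide whether a constant difference is the whole source of the regions called higher. A change with ADAR2 in these regions was not tested apart from the libraries or from the amount of RNA, and stays open. No input library from cells with SRSF9 alone was used here.

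The 52 windows with a larger share of peaks found only without ADAR2 may in part reflect several neighbouring peaks counted as independent. With peaks of a class within 1 kb made into 1, which left 4127 peaks only without ADAR2 and 48808 only with it, 14 windows passed, below the bound set before that result was seen. Merging also lowers the number of peaks per window, so part of that fall may come from fewer peaks, which was not tested apart. A biological difference between the conditions at the windows that stayed was not tested.

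Of the values with at most 3 decimals, many in 3 of the libraries fell on log2 ratios of whole numbers of at most 6 over at most 3, plus the constant of the column, within 0.0012: 52.9% in the first SRSF9-only library and 47.8% and 49.5% in those with ADAR2, against 44.7%, 38.5% and 39.3% at the next best constant and 0.0117%, 0.0189% and 0.0148% at the median of all constants tried. The second SRSF9-only library showed no clear constant, with 43.8% of its 6679 values of at most 3 decimals, out of 8565, at the best. At the next best it was 43.2% and at the median of all constants tried 0.284%, for ratios of up to 60 over 2. Its values thus also fell on such ratios, but the best constants fit them nearly equally. Ratios of small read numbers would give such steps, and the constants themselves are not firmly placed.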
